A study of Homo sapiens with 4 samples.

How the data were processed

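RNA-seq values came from U937 macrophages infected with EPEC, in 2 libraries under simulated microgravity and 2 under normal gravity, grouped by their titles. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit for Illumina sequencing. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used with the genome build GRCh38 (hg38). The strandedness and the annotation release are not given in the sources used here. All 28612 gene identifiers that matched GENCODE release 29 had the same start and end there, and 248 other rows carry no gene name.

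The authors deposited 1 table of 28860 rows with a normalised signal per gene and library. In each column every value was a whole multiple of the smallest value above 0, so the deposited signal is a read count divided by 1 size factor per library. Dividing by that step gave whole reads for 100% of values within 1e-06. For normal-gravity replicate 1 the step is 1.00, so near to 1 that an automated test for whole reads, which skips such steps because rounding can make them, did not accept that column. Its values are not rounded, and each was a whole multiple of the step within 1e-08, so its reads were recovered in the same way. Recovered reads were used for depth, for other scalings and for count tests run as alternatives, and the main test does not use them. The table also holds the authors' log2 fold changes, and the authors' deposited p-values and adjusted p-values, with no p-value in 210 rows, and a gene length. How these were fitted is not given in the sources used here.

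The planned main test was edgeR on counts, with limma-trend as the planned test should the values be normalised. Since the signal is normalised, limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1) was used, with the group as the only term and a filter by filterByExpr with a minimum count of 10 applied to the deposited values, which kept 16153 genes. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and ± after a log2 fold change is its standard error. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The test had 11.6 degrees of freedom in all. Gene lists, 42 fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested (38 lists), with an estimated correlation and with fry as alternatives. Genes were named by a rule fixed before the data were examined: the 5 largest rises and 5 largest falls among called protein-coding genes with a mean of at least 5 CPM; for each list 2 to 4 members in order of adjusted p among those past the test, filled up by the most abundant members where fewer than 2 passed; and TNF, IL1B, IL6, CXCL8, IL10, TLR4 and CD14.

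On data simulated with the means, depths and dispersions of this comparison (15661 genes passing the filter), the test recovered 35.4% of 65 genes changed 1.5-fold, 69.2% of 65 changed 2-fold and 95.5% of 66 changed 4-fold, and it called 15 of 15465 unchanged genes. Among 20 lists, camera called 5 of 5 shifted lists and 0 of the others. With an estimated correlation it also called the 5 shifted lists. The simulated genes were drawn independently and most were unchanged, so these calls do not show how the test performs on lists of correlated genes. In the real data 50.4% of genes were called, which makes the Benjamini-Hochberg cut less strict than in the simulation. The simulated shares of recovered and falsely called genes therefore do not carry over to the main test. The depth ran from 22838003 to 33317794 reads per library. Counting intervals (exact binomial, 95%) cover counting error only.

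The replicates of a group were checked for duplicates by a chi-square test over genes with at least 20 reads, which gave 19.7 per degree of freedom under normal gravity and 7.96 under simulated microgravity, so no library was a copy of another. Alternatives were RLE (DESeq2 1.42.0), upper-quartile and TMM factors, library totals, other filters, a replicate block, leaving out each library, DESeq2, limma-voom, edgeR 4.0.16 quasi-likelihood tests on recovered reads with and without legacy quasi-dispersion, a test against a 1.2-fold change, a fold minimum, protein-coding genes only, other pseudocounts (0.5 and 10), and removal from each library of a spline trend on GC content and length of the longest GENCODE transcript, known for 98.8% of tested genes. The edgeR quasi-likelihood test called 3846 genes higher and 4478 lower. No sample was left out of the comparison.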

Results

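RNA was profiled by Illumina sequencing in macrophages of the U937 line, an established human monocytic line that originated from a histiocytic lymphoma, after infection with enteropathogenic Escherichia coli (EPEC), a gut pathogen that attaches to host cells and injects proteins into them. The 4 libraries formed 2 groups of n = 2: infected macrophages held under simulated microgravity, with a pretreatment of 3 days, and infected macrophages held under normal gravity. The design text speaks of triplicates, and 2 libraries per group were analysed here. Reads assigned to genes numbered 22838003 and 29131652 in the normal-gravity libraries and 33317794 and 24643940 in the simulated-microgravity libraries. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Across the 16153 genes tested, log2 values correlated at 0.988 or more within a group and at 0.933 or less between groups. These are correlations across genes, which are not independent replicates.

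The comparison asked how the transcriptome of infected macrophages differed between simulated microgravity and normal gravity. Every library was infected, so a changed response to the bacterium cannot be told apart from a difference present before infection. Genes of cell division were lower under simulated microgravity: all 34 tested members of the mitosis list fell, with a median log2 fold change of -2.47. Most chemokine genes, most matrix metalloproteinase genes and 12 of 21 pro-inflammatory cytokine genes were higher, among them CXCL8, IL1B, IL6, CXCL5 and MMP10. TNF, which encodes a cytokine that starts inflammation, fell (log2 fold change -0.84), and IL10 and TLR4 did not pass the test. Most genes of cholesterol synthesis and uptake and most immediate-early genes were lower. In total 3781 genes were higher and 4363 lower at a Benjamini-Hochberg adjusted p under 0.05 by limma-trend, which is 50.4% of the genes tested, and 1765 and 2178 of them changed by a log2 fold change of at least 1. Higher genes made up 46.4% of the calls, 31.4% when libraries were scaled by their totals only and 54.4% with upper-quartile factors, so the direction of the excess depends on the scaling. Without simulated-microgravity replicate 2 the number of higher genes was 2353.

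The genes were chosen by a rule fixed before the data were examined, and for all 166 of them that passed the test both libraries of one group lay above both of the other. Passing the test nearly fixes that separation; over all tested genes it was found in 75.6%, and chance gives 33.3%. The largest rise was that of SERPINB4, a serine protease inhibitor of the squamous cell carcinoma antigen pair, with a log2 fold change of 9.51 ± 0.49 (SE; adjusted p = 4.88e-08). With 3103 reads against 3, its ratio was 1046, with a 95% counting interval of 358 to 5074, and its reads cannot be parted with certainty from those of its near-identical neighbour SERPINB3. SERPINB7 of the same family reached 1632 ± 39.1 normalised reads (mean ± SD, n = 2) under simulated microgravity against 3.37 ± 2.32. IL2RA, the alpha chain of the interleukin-2 receptor, rose from 15.4 ± 2.25 to 2890 ± 131.2, with a log2 fold change of 7.46 ± 0.17 and an adjusted p of 3.13e-10. CXCL5, a neutrophil-attracting chemokine, rose by 7.39 ± 0.22 on the log2 scale (adjusted p = 2.35e-09). The largest falls were those of RTN4R, the Nogo receptor, at -5.52 ± 0.30, CYSLTR1, a receptor for cysteinyl leukotrienes, at -4.91 ± 0.20, GPR34, a lysophosphatidylserine receptor, at -4.80 ± 0.38, SAPCD2 at -4.35 ± 0.32 and KIF20A, a kinesin of cytokinesis, at -4.32 ± 0.19. Their adjusted p-values ran from 9.18e-09 for CYSLTR1 to 1.23e-06 for GPR34, with KIF20A at 1.49e-08.

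By the coordinates of the deposited table (GRCh38), SERPINB4 (ENSG00000206073) lies on chromosome 18 at 63637259 to 63644298 and SERPINB7 (ENSG00000166396) on the same chromosome at 63752935 to 63805376. IL2RA is on chromosome 10 at 6010689 to 6062370 and CXCL5 on chromosome 4 at 73995642 to 73998779. RTN4R is on chromosome 22 at 20241415 to 20283246, CYSLTR1 on chromosome X at 78271464 to 78327691, GPR34 on chromosome X at 41688973 to 41697277, SAPCD2 on chromosome 9 at 137062124 to 137070588 and KIF20A on chromosome 5 at 138178719 to 138187715. All of these are annotated as protein-coding. In what follows a bracketed value after a gene that fell is its log2 fold change.

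**Figure D1:**
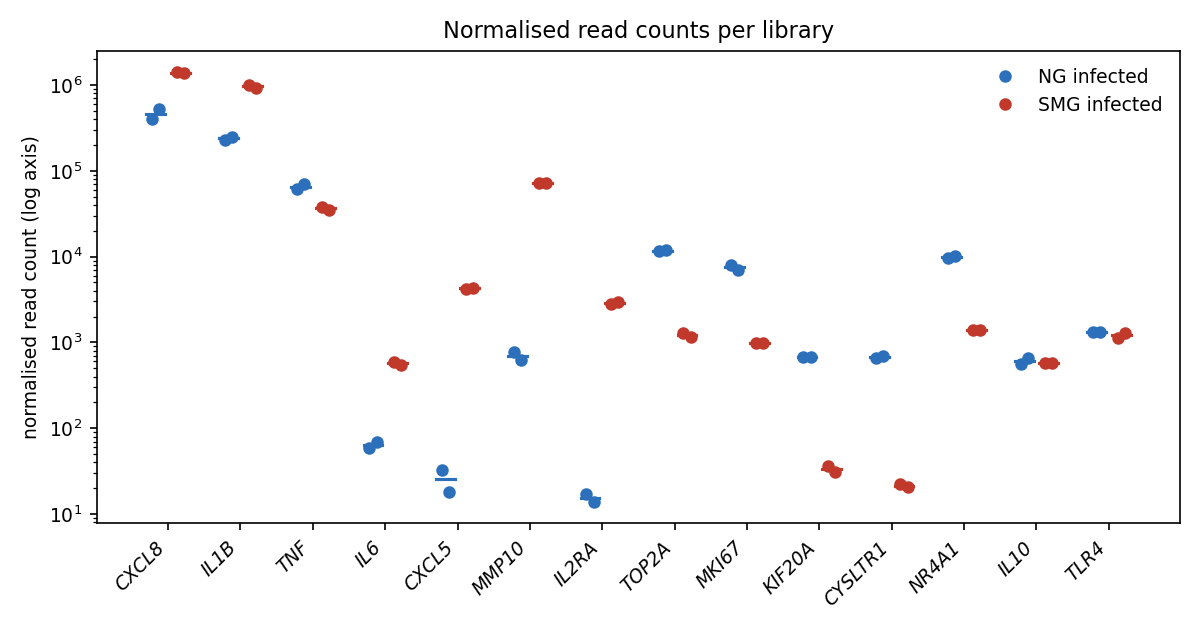
Normalised read counts (log axis) of 14 genes, with 1 point per library and a line at the mean of each group of 2. The 2 groups do not overlap for any gene shown except IL10; CXCL8, IL1B, IL6, CXCL5, MMP10 and IL2RA are higher under simulated microgravity, and TLR4, like IL10, did not pass the test.

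Of 21 tested pro-inflammatory cytokine genes, 12 rose, 6 fell and 3 did not pass. IL1A rose by 4.14 ± 0.15 on the log2 scale, EBI3, a subunit of interleukin-27 and interleukin-35, by 4.28 ± 0.17, TNFSF15 by 3.17 ± 0.13 and INHBA, the activin A subunit, by 3.47 ± 0.14, all with an adjusted p of 1.15e-08 or less. IL1B rose by 2.01 ± 0.24 (adjusted p = 3.53e-05) and took 3.54 ± 0.113% of reads under simulated microgravity against 0.991 ± 0.00217% under normal gravity (n = 2 each). IL6 rose by 3.15 ± 0.18 (adjusted p = 8.39e-08), from 63.8 ± 6.58 to 571 ± 34.8 normalised reads. TNF fell (-0.84 ± 0.15, adjusted p = 0.000692), and IL10 stood at 580 ± 4.12 against 612 ± 76.4 normalised reads (adjusted p = 0.685). By camera with a preset correlation the cytokine list was higher than other genes, with a median log2 fold change of 1.01 (adjusted p = 0.0277), and with an estimated correlation its adjusted p was 0.679. The call ended with upper-quartile scaling (median 1.11) and with the trend on GC content and length removed (1.10), although neither median was smaller. Over all settings the median ran from 0.77, without normal-gravity replicate 2, to 1.65, with the CPM filter.

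Chemokine genes rose in 16 of 19 cases, fell in 2 and did not pass in 1, with a median log2 fold change of 0.88 (camera adjusted p = 1.67e-06). The list had an adjusted p = 0.607 with an estimated correlation. CCL1 rose by 3.93 ± 0.11, CXCL6 by 4.03 ± 0.15 and CCL7, a monocyte attractant, by 2.26 ± 0.13. CXCL8, the main neutrophil attractant of human cells, rose by 1.59 ± 0.29 (adjusted p = 0.000702) and was the most abundant gene, with 5.09 ± 0.0302% of reads against 1.92 ± 0.234%. The 10 most abundant genes together took 16.3 ± 0.201% of reads under simulated microgravity and 7.43 ± 0.481% under normal gravity. Adjusted over the list alone, 12 cytokine genes rose and 8 fell, and 17 chemokine genes rose and 2 fell. Reads of CCL3 and CCL3L1, and of CCL4 and CCL4L2, cannot be parted with certainty.

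The authors' deposited table, which comes with fold changes of its own, differed from these values for many inflammatory genes and for some genes of other lists. In the authors' deposited table the log2 fold change was 0.11 for IL1B, 0.21 for CXCL8, -0.50 for IL6, -0.30 for CD14 and -1.54 for TNF. There IL1B and CXCL8 had an adjusted p of 1.0 and TNF one of 0.549, while IL6 and CD14 had no p-value. Other genes named here that had no p-value there included SERPINB7, IL2RA, CXCL5, CYSLTR1, IL1A, CCL1 and MMP10. The median of the authors' deposited table was -0.55 over the cytokine list and -0.14 over the chemokine list. Of the genes called here, 10 of the 18 chemokine genes and 8 of the 18 cytokine genes had the opposite sign there. Of 21 metalloproteinase and matrix genes called here 19 had the same sign, with a median of 0.79 in the authors' deposited table. Of all calls 87.1% had the same sign. The sign was opposite for 4 of 10 called promonocytic and granule genes and 4 of 11 called mitochondrially encoded genes. It was also opposite for 7 of 20 called nuclear respiration genes and 5 of 15 called stress response genes. Single genes with the opposite sign there included HSPA6 (-2.24), MT-CO1 (-0.48), CHI3L1 (0.98) and LYZ (0.47). For the mitosis list the authors' deposited table had a median of -1.80, and all 34 members had the same sign as here. Of these 34, 0 had an adjusted p under 0.05 there, with 0.514 for TOP2A and 0.366 for MKI67. The same 4 libraries are in that table, so equal signs are not independent support. The authors' deposited table held 70 genes with an adjusted p under 0.05, of which 39 were higher and 31 lower. Of these, 69 were tested here, and all 69 were called in the same direction. GZMB, which encodes granzyme B, had the smallest adjusted p in the authors' deposited table, 3.75e-09, with a log2 fold change of 3.97.

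**Figure D2:**
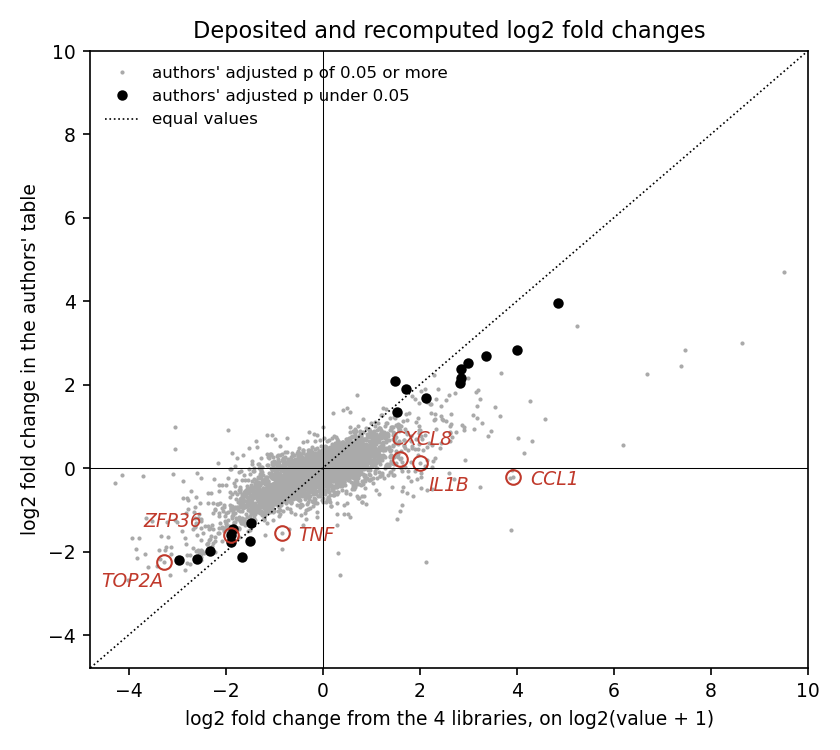
Log2 fold changes from the 4 libraries (horizontal axis, on the log2(value + 1) scale) against those of the authors' deposited table (vertical axis) for 6281 tested genes with a mean normalised count of at least 500; black points have an authors' adjusted p under 0.05, red circles mark named genes and the dotted line marks equal values. The slope of the deposited values on those from the 4 libraries is 0.427, and IL1B, CXCL8 and CCL1 lie near 0 on the vertical axis.

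Matrix metalloproteinase and matrix genes rose in 16 of 25 cases, fell in 5 and did not pass in 4 (median log2 fold change 0.90, camera adjusted p = 0.00161). The adjusted p was 0.607 with an estimated correlation. MMP10, stromelysin 2, rose by 6.69 ± 0.13, from 699 ± 98.2 to 72016 ± 913 normalised reads. MMP8, a neutrophil collagenase, rose by 3.24 ± 0.11 and MMP12, macrophage elastase, by 5.34 ± 0.28, while MMP2, gelatinase A, fell (-2.61 ± 0.14). Adjusted over the list alone, 17 rose and 5 fell.

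In the mitosis list 34 of 34 tested members fell, both over all genes and adjusted over the list alone (camera adjusted p = 9.54e-23, and adjusted p = 0.607 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, fell (-3.27 ± 0.11), DLGAP5 (-3.35 ± 0.13), MKI67, the Ki-67 proliferation marker (-2.92 ± 0.11) and CENPF, a kinetochore protein gene (-3.37 ± 0.14). In the list of G1/S and DNA replication 34 of 36 fell and 2 did not pass, with a median of -1.14 (camera adjusted p = 8.84e-12, and adjusted p = 0.607 with an estimated correlation) and the same counts adjusted over the list alone. UHRF1, which maintains DNA methylation, fell (-2.58 ± 0.16), E2F2 (-2.75 ± 0.23), LIG1, DNA ligase 1 (-1.46 ± 0.13) and RRM2, a ribonucleotide reductase subunit (-1.47 ± 0.14). Of 24 tested p53 target and arrest genes 11 rose, 6 fell and 7 did not pass (7 fell when adjusted over the list alone), and the list was not called (adjusted p = 0.204). GADD45A rose by 1.74 ± 0.12 and GADD45B fell (-2.50 ± 0.15). Tubulin and microtubule genes fell in 13 of 21 cases and rose in 2 (15 fell and 2 rose when adjusted over the list alone), with a median of -0.57 (camera adjusted p = 0.00125). That list had an adjusted p = 0.645 with an estimated correlation. CKAP5 fell (-1.70 ± 0.11) and STMN1, which destabilises microtubules (-2.13 ± 0.14).

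**Figure D3:**
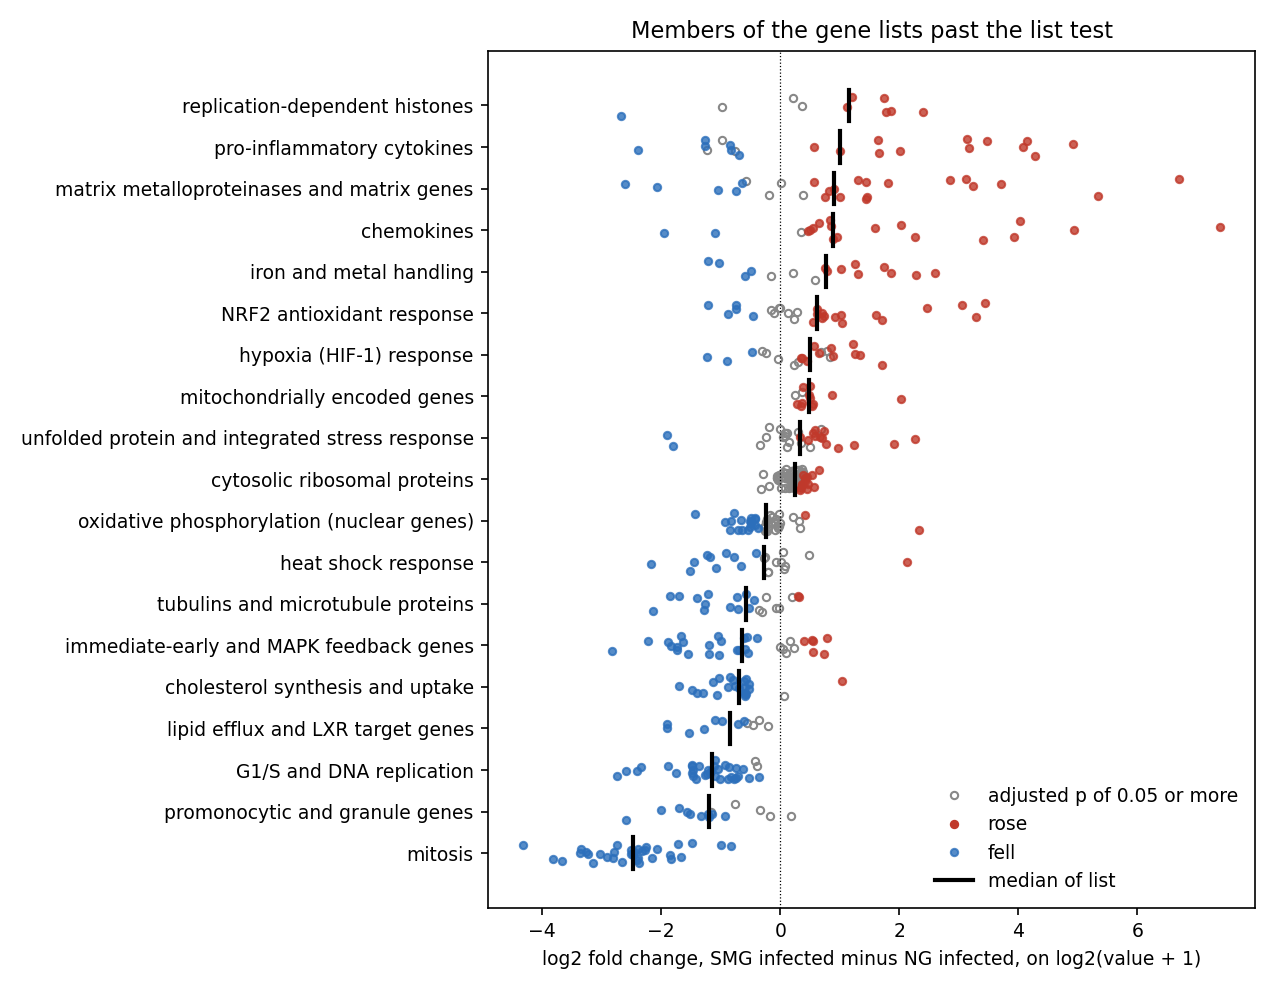
Log2 fold changes (horizontal axis, simulated microgravity minus normal gravity, on the log2(value + 1) scale) of all tested members of the 19 gene lists past the list test, with 1 point per gene, filled where the gene passed and open where it did not, and a black line at the median of each list. The mitosis list lies furthest to the left with a median of -2.47, and none of its members rose.

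Of 23 tested genes of cholesterol synthesis and uptake 21 fell, 1 rose and 1 did not pass (median -0.69, camera adjusted p = 2.84e-06), and of 12 lipid efflux and LXR target genes 8 fell, none rose and 4 did not pass (median -0.84, camera adjusted p = 0.000568). Both lists had an adjusted p = 0.607 with an estimated correlation, and the counts were the same adjusted over the list alone. DHCR7, which carries out the last reduction step of one branch of cholesterol synthesis, fell (-1.39 ± 0.12), and so did ACAT2 (-1.70 ± 0.14). FASN, fatty acid synthase, fell (-1.90 ± 0.11) and FABP5, a fatty acid carrier (-1.89 ± 0.12).

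Immediate-early and MAPK feedback genes fell in 21 of 32 cases, rose in 6 and did not pass in 5 (median -0.65, camera adjusted p = 0.00135). The adjusted p was 0.645 with an estimated correlation, and the counts were the same adjusted over the list alone. NR4A1, a nuclear receptor induced within minutes of stimulation, fell (-2.83 ± 0.11), EGR3 (-2.22 ± 0.12), ZFP36, whose protein promotes decay of cytokine mRNAs (-1.89 ± 0.12) and FOSB (-1.84 ± 0.13). Of 15 tested promonocytic and granule genes 10 fell, none rose and 5 did not pass (11 fell when adjusted over the list alone), with a median of -1.19 (camera adjusted p = 0.000493). That list had an adjusted p = 0.607 with an estimated correlation. LYZ, lysozyme, fell (-1.52 ± 0.11) and MYB, a transcription factor of immature blood cells (-2.59 ± 0.23).

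Stress and metal genes were mixed in direction. Of 27 NRF2 antioxidant genes 15 rose, 5 fell and 7 did not pass (median 0.62, camera adjusted p = 0.00477, and adjusted p = 0.683 with an estimated correlation). SLC7A11, the cystine importer, rose by 3.29 ± 0.15, TRIM16L by 2.46 ± 0.17 and TXNRD1, thioredoxin reductase 1, by 1.61 ± 0.12. Of 30 genes of the unfolded protein and integrated stress response 13 rose, 2 fell and 15 did not pass (14 rose when adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.00653, and adjusted p = 0.683 with an estimated correlation). DNAJB9, a chaperone of the endoplasmic reticulum, rose by 2.26 ± 0.17, and PHGDH, the first enzyme of serine synthesis, fell (-1.81 ± 0.15). Of 22 hypoxia genes 11 rose, 3 fell and 8 did not pass (median 0.51, camera adjusted p = 0.019, and adjusted p = 0.607 with an estimated correlation). BNIP3L, a mitophagy receptor, rose by 1.25 ± 0.11 and ADM, adrenomedullin, by 1.34 ± 0.13. Of 16 iron and metal genes 9 rose, 4 fell and 3 did not pass (median 0.77, camera adjusted p = 0.0319, and adjusted p = 0.607 with an estimated correlation). The metallothionein genes MT2A and MT1E, whose paralogs can share reads, rose by 2.60 ± 0.11 and 1.87 ± 0.13. Of 21 heat shock genes 10 fell, 1 rose and 10 did not pass (median -0.28, camera adjusted p = 0.0208, and adjusted p = 0.799 with an estimated correlation). HSPA1B, which shares reads with HSPA1A, fell (-2.16 ± 0.15), and HSPA6 rose by 2.13 ± 0.15. For the NRF2, hypoxia, metal and heat shock lists the counts were the same adjusted over the list alone. The heat shock call was lost without normal-gravity replicate 2 (median -0.18) and without simulated-microgravity replicate 2 (median -0.33), and the call of the stress response list without normal-gravity replicate 1 (median 0.31). The hypoxia list stayed past the test without normal-gravity replicate 2 and with library totals, but with a smaller median (0.32 and 0.33), as did the stress response list with library totals (0.16). For the heat shock list the median was -0.46 with library totals and -0.18 with upper-quartile factors. The metal call was lost with upper-quartile scaling (median 0.87), with the trend on GC content and length removed (0.81) and with no filter on low values (0.58). Of these only the last was below the reported median.

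Of 42 nuclear genes of oxidative phosphorylation 18 fell, 2 rose and 22 did not pass (median -0.24, camera adjusted p = 0.019, and adjusted p = 0.823 with an estimated correlation), with the same counts adjusted over the list alone. SDHA, the flavoprotein of succinate dehydrogenase, fell (-1.43 ± 0.11), and NDUFV2 rose by 2.33 ± 0.27. Of the 13 genes encoded in mitochondrial DNA 11 rose, none fell and 2 did not pass (12 rose when adjusted over the list alone), with a median of 0.49 (camera adjusted p = 0.00135, and adjusted p = 0.607 with an estimated correlation). MT-CO1 rose by 2.04 ± 0.14 and MT-CYB by 0.87 ± 0.13. Mitochondrial genes took 1.82 ± 0.103% of reads under simulated microgravity and 1.30 ± 0.213% under normal gravity. Of 76 ribosomal protein genes 13 rose, none fell and 63 did not pass (1 rose when adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00161, and adjusted p = 0.827 with an estimated correlation). RPS28 rose by 0.66 ± 0.13 and RPL23A by 0.46 ± 0.11. Of 10 replication-dependent histone genes, whose transcripts mostly lack poly-A tails and which served as a check of RNA quality, 6 rose, 1 fell and 3 did not pass, over all genes and adjusted over the list alone (median 1.16, camera adjusted p = 0.0443, and adjusted p = 0.607 with an estimated correlation). HIST1H2BK rose by 1.77 ± 0.16 and HIST1H2AC by 1.86 ± 0.21. The nuclear respiration call was lost in 6 of 16 settings: without normal-gravity replicate 2 (median -0.14), without simulated-microgravity replicate 1 (-0.30) or 2 (-0.22), with the replicate number as a block, with fry and with edgeR. Its median was -0.39 without normal-gravity replicate 1, -0.42 with library totals and -0.14 with upper-quartile factors. The ribosomal call was lost with fry, without normal-gravity replicate 1 (median 0.08) and without simulated-microgravity replicate 1 (0.17), and its median was 0.42 without normal-gravity replicate 2. The histone call was lost in 7 of 16 settings: without normal-gravity replicate 1 (median 0.87) or 2 (0.99), without simulated-microgravity replicate 1 (0.99), with upper-quartile factors, with no filter on low values (0.07), with edgeR and with the trend on GC content and length removed. With the trend on GC content and length removed, the median of the mitochondrially encoded genes was 0.01 and the call was lost. With library totals the mitochondrially encoded and ribosomal lists stayed past the test with smaller medians (0.31 and 0.07). RPL23A did not pass without simulated-microgravity replicate 1 (0.45) or 2 (0.48).

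Lists of pathogen sensing were not called by camera. Fry tests a list against no change and not against other genes. By fry the inflammasome and MHC class II lists passed (adjusted p = 0.0281 each), as did the Toll-like list (0.0496). Of 30 NF-kB target genes 9 rose, 11 fell and 10 did not pass (camera adjusted p = 0.815): TNIP3 rose by 6.20 ± 0.21, GCH1 by 1.76 ± 0.12 and CD40 by 2.99 ± 0.28, and NFKBIZ fell (-1.21 ± 0.12). Of 30 genes of Toll-like and NOD receptor signalling 12 rose, 9 fell and 9 did not pass (adjusted p = 0.413). RIPK2 rose by 1.69 ± 0.13, TLR2 by 1.81 ± 0.15 and CD14, the lipopolysaccharide co-receptor, by 1.69 ± 0.18 (adjusted p = 1.09e-05), while TLR4 stood at 1215 ± 124.1 against 1328 ± 11.9 normalised reads (adjusted p = 0.388). Of 19 inflammasome genes 9 rose, 2 fell and 8 did not pass (10 rose when adjusted over the list alone; adjusted p = 0.0613), with PYCARD, the ASC adaptor, falling (-1.77 ± 0.15) and TXNIP rising from 613 ± 68.3 to 1730 ± 17.2 normalised reads. Of 34 interferon-response genes 11 rose, 14 fell and 9 did not pass (adjusted p = 0.995), and IFIT2 rose by 3.00 ± 0.17 and ISG20 by 1.73 ± 0.15. Of 18 genes of MHC class I presentation 2 rose and 5 fell (adjusted p = 0.308), and the immunoproteasome genes PSMB9 and PSMB8 fell (-1.99 ± 0.18 and -1.34 ± 0.15). Of 14 genes of MHC class II presentation and co-stimulation 4 rose and 5 fell (adjusted p = 0.995), CD274, the PD-L1 gene, rising by 3.40 ± 0.40. The counts of the other 5 lists in this group were the same adjusted over the list alone.

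Macrophage lists were not called by camera either. By fry the mature macrophage markers (adjusted p = 0.0122) and the phagocytic and scavenger receptors (adjusted p = 0.0338) passed. Of 19 mature macrophage markers 3 rose, 8 fell and 8 did not pass (camera adjusted p = 0.0605), with CHI3L1 falling (-3.05 ± 0.11) and CEBPA, a myeloid transcription factor (-2.64 ± 0.15). Of 16 genes of alternatively activated macrophages 5 rose and 4 fell (adjusted p = 0.859), and the efferocytosis receptor MERTK fell (-3.64 ± 0.17) and STAB1 (-2.72 ± 0.14). Of 26 phagocytic and scavenger receptors 8 rose and 12 fell (adjusted p = 0.613), TREM1, which amplifies inflammation, rising by 3.56 ± 0.12. Of 37 lysosomal genes 9 rose and 14 fell (adjusted p = 0.213), and ATP6V0D2 fell (-3.79 ± 0.17) and CTSD, cathepsin D (-2.15 ± 0.14). Of 33 autophagy genes 13 rose and 5 fell (adjusted p = 0.109), with ATG2A rising by 1.05 ± 0.13 and ATG7 by 0.86 ± 0.11. Of 10 oxidative burst genes 3 rose and 3 fell (adjusted p = 0.895), and CYBB, the catalytic NADPH oxidase subunit, fell (-1.65 ± 0.11) and HVCN1 (-2.15 ± 0.36). Of 50 genes of the actin cytoskeleton and adhesion 6 rose and 19 fell (adjusted p = 0.107), ITGA4 falling (-2.30 ± 0.12) and ITGB3, with 294 reads against 4, rising by 5.61 ± 0.38. Of 24 glycolysis genes 6 rose and 6 fell (adjusted p = 0.996), with PFKFB4 falling (-1.38 ± 0.12) and PFKL (-0.68 ± 0.12). With the trend on GC content and length removed PFKL had a log2 fold change of -0.14 and no longer passed. Of 28 apoptosis regulators 7 rose and 9 fell (8 rose when adjusted over the list alone; adjusted p = 0.800), CFLAR, an inhibitor of caspase-8, rising by 1.51 ± 0.12 and CASP6 falling (-2.47 ± 0.25). The counts of the other 8 lists in this group were the same adjusted over the list alone. For the interferon, alternatively activated, oxidative burst, glycolysis and MHC class II lists the median, the mean and the direction of the test differed in sign.

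Markers of other cell types were few and moved apart. Of 7 tested T and NK cell markers 3 rose, 3 fell and 1 did not pass (camera adjusted p = 0.423), with GZMB rising by 4.85 ± 0.15, NCAM1 by 2.64 ± 0.13 and TRAC falling (-1.91 ± 0.18). Of 7 neutrophil and mast cell markers 1 rose and 6 fell (adjusted p = 0.0537). By fry both of these lists passed (adjusted p = 0.0281 each). MMP8 rose, and the tryptase genes TPSAB1 and TPSB2, which share reads, fell (-1.89 ± 0.16 and -2.50 ± 0.27). The remaining lists had fewer than 5 tested members and no list test. All 3 tested B and plasma cell markers fell, among them CD79A (-2.59 ± 0.43) and PAX5 (-2.37 ± 0.40). Both tested epithelial markers rose, KRT7 by 0.89 ± 0.14 and MUC1 by 0.55 ± 0.20. The MUC1 call was lost in 7 settings: without normal-gravity replicate 1 (0.50), without simulated-microgravity replicate 1 (0.50) or 2 (0.60), with the replicate number as a block, with library totals, with no filter on low values and with DESeq2. Of 4 fibroblast and endothelial markers 2 fell, PECAM1 (-2.29 ± 0.11) and VWF (-3.38 ± 0.18), and 3 fell when adjusted over the list alone. Of 3 erythroid and megakaryocyte markers 1 rose: PPBP, a platelet chemokine gene, went from 559 ± 205 to 8681 ± 226 normalised reads (adjusted p = 3.08e-08), and GP1BA stood at 39.6 ± 8.17 against 33.2 ± 12.6. Of 6 nuclear and RNA polymerase III transcripts 1 rose (adjusted p = 0.347), and none when adjusted over the list alone: MALAT1 had a log2 fold change of 0.76 ± 0.25 and NEAT1 one of 0.76 ± 0.30 (adjusted p = 0.0502). Both rested on the normal-gravity libraries, which differed in NEAT1 (10899 and 4371 normalised reads) and MALAT1 (3877 and 1866): without replicate 1 of that group MALAT1 stood at 1.28 and NEAT1 at 1.42, and without replicate 2 at 0.23 and 0.11. The MALAT1 call was lost in 7 settings: without normal-gravity replicate 2, with library totals, with TMM factors, with no filter on low values, with DESeq2 and with both edgeR tests. NEAT1 passed without normal-gravity replicate 1, without simulated-microgravity replicate 1 (0.84) or 2 (0.68), with the replicate number as a block, with the CPM filter, with a pseudocount of 10 and with the trend on GC content and length removed.

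The strandedness of the counting is not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart. None of the 19 list calls held with an estimated correlation between genes, where the smallest adjusted p was 0.607. The hypoxia list and the lipid efflux and LXR list lost their calls too, although their estimated correlation was -0.04 each. Correlation between members therefore does not account for the loss in these lists.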

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

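The tests of this part were chosen after the result was seen. The authors' deposited table holds fold changes that the report's comparison did not use, and these drew attention because all 798 genes with 0 reads in all 4 libraries carry a fold change other than 0 there. A fit to these 4 libraries alone has nothing to estimate for such genes, so a candidate explanation is that the authors' fit held further libraries, for instance the third of each group that the design text implies. These 798 values argue against a fit to these 4 libraries alone. The count is also what prompted the explanation of further libraries, so it is no test of that explanation, which stays open. Shrinkage of fold changes fitted to these 4 libraries is argued against, because 81 of 1013 genes called here with a mean of at least 500 and a log2 change of at least 1 have the opposite sign in the authors' column. Another scaling does not account for it either, since 84 have the opposite sign after both columns are centred, against 81 before. Which further libraries the authors' fit held, if any, and how they differed from these 4, stays open, and no biological explanation was tested.

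The gap between both sets of fold changes was uneven across gene groups. Of the 19 lists called here 16 had a median of the same sign in the authors' deposited table, and 3 had the opposite sign: pro-inflammatory cytokines (-0.55 there), chemokines (-0.14) and iron and metal genes (-0.01). The last lies above the median of that column over all tested genes (-0.04), so its opposite sign goes when the column is centred, and 10 of its 13 called members had the same sign in both. All 34 mitosis genes, all 36 genes of G1/S and DNA replication and 22 of 23 cholesterol genes had the same sign in both. The authors' adjusted p was under 0.05 for 0 of the mitosis genes, 3 of the G1/S and DNA replication genes and 0 of the cholesterol genes. If the 798 genes do mark further libraries in the authors' fit, the rise of cytokine and chemokine genes may not extend to those libraries, while the fall of cell-cycle genes may; that was not tested here.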

How the results depend on the processing

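Pseudocounts, TMM factors, the edgeR quasi-likelihood test on recovered reads and the removal of the GC and length trend were chosen after seeing the data; the other alternatives were fixed before. Under scalings, filters, pseudocounts, trend removal, the replicate block and other tools without a fold minimum (14 settings) the number of genes higher ran from 2521 to 4576 and lower from 3773 to 5506. A minimum log2 fold change of 1 left 1765 higher and 2178 lower, by its own construction. Leaving out 1 library gave 2353 to 4228 higher, 3343 to 4744 lower, 9 to 11 lists higher and 9 to 13 lists lower; the lone library was assumed to vary like the other group, and 2353 came without simulated-microgravity replicate 2, where fewer samples were tested. The replicate numbers are shared by the groups but nothing says they mark a shared culture. Deviations of same-numbered libraries correlated at -0.365 across genes. With the replicate number as a block 3292 genes were higher, 3931 lower, 10 lists higher and 9 lower. The block ended the calls of the nuclear respiration list (adjusted p = 0.0576) and of MUC1, and 1 list not called in the main test was called lower. With fry 13 lists were higher and 10 lower. With an estimated correlation 0 lists were higher and 0 lower. The simulated lists were found with it, but their genes were drawn independently, so they say nothing of its power here. In the real lists the estimated correlation was 0.41 for mitosis, 0.64 for G1/S and DNA replication, 0.90 for ribosomal proteins and -0.04 for hypoxia genes. Lists with a value below 0, such as the hypoxia list, lost their calls as well, so correlated members alone do not account for the loss. Its cause was not tested. With the GC and length trend removed 6 lists were higher, and 4 lists lost their calls: the mitochondrially encoded genes (median 0.49 to 0.01), histones (1.16 to 0.81), and cytokines (1.01 to 1.10) and metal genes (0.77 to 0.81), whose medians did not shrink; the cause was not tested beyond the removal itself.

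Upper-quartile scaling moved the median log2 fold change of all tested genes by 0.10 and library totals by -0.18, relative to the authors' factors. Apart from the estimated correlation, the adjusted p over 16 settings ran up to 0.375 for nuclear respiration genes (6 calls lost), 0.214 for histones (7 lost), 0.381 for ribosomal proteins (3 lost), 0.130 for heat shock genes (3 lost; 0.130 is from fry, which tests a list against no change and not against other genes, and camera reached 0.0849), 0.0696 for metal genes (3 lost), 0.0750 for cytokines (2 lost), 0.779 for mitochondrially encoded genes (1 lost) and 0.0618 for the unfolded protein and integrated stress response (1 lost); the other 11 called lists were lost in none of the 16. Of 2987 values of the 166 called genes under the alternatives 2959 kept direction and call, 27 lost the call and 1 changed sign: MT-ND4L, -0.20 with the GC and length trend removed. IL10, never past the test, had a log2 fold change of 0.031 with upper-quartile factors, 0.054 without normal-gravity replicate 2 and -0.20 to 0.054 over the leave-one-out settings, and GP1BA ran from -0.10 (without normal-gravity replicate 2) to 0.67 over the same settings; the cause was not tested.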

Other observations

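The tests on a few genes taking most of the counts, those of the GC trend over whole lists of inflammatory genes, and the gene families were chosen after the results were seen; the families were taken from shared symbol prefixes, and 224 with at least 8 tested protein-coding members were tested by camera, of which 9 passed and 0 passed with an estimated correlation (adjusted p = 0.993 for each). Of 24 genes with the prefix SEC, some of which encode parts of the translocon of the endoplasmic reticulum and of the COPII coat, 12 rose, none fell and 12 did not pass (median log2 fold change 0.50, adjusted p = 0.0137). With library totals the median of the SEC genes was 0.33. SEC61G, SEC61A1 and SEC61B, the subunits of the translocon, rose by 1.38 ± 0.11, 1.10 ± 0.12 and 1.08 ± 0.13. Of 9 serpin B genes 7 rose and none fell (median 1.09, adjusted p = 0.0105), and several of them lie side by side on chromosome 18.

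Other families were lower. Of 21 nucleoporin genes with the prefix NUP 14 fell and 1 rose (median -0.61, adjusted p = 0.0207), with NUP210 falling from 5536 ± 596 to 343 ± 10.2 normalised reads. Of 31 kinesin genes 18 fell and 4 rose (adjusted p = 0.00958). Of 8 HOXA genes 7 fell and none rose, with a median of -1.87 that did not pass the family test (adjusted p = 0.0708); HOXA9 and HOXA10, transcription factors of myeloid progenitors, fell (-1.66 ± 0.20 and -2.08 ± 0.24).

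The fall of the mitosis genes was weighed against technical causes. Removing the trend on GC content and length, known for 100% of the list, left a median of -2.56 (quartiles -2.97 and -2.21), against -2.47 before. The higher share of reads in a few genes moves all genes of a library by 1 factor, and the median of the list minus that of all tested genes was -2.48. The first value argues against the trend. The second repeats the list test, since the median of all tested genes was already 0.01 under the authors' factors. It shows only that 1 factor per library cannot set the list apart from other genes. A lower share of dividing cells under simulated microgravity is the hypothesis that stays open; a difference between cultures in density or growth also stays open, and neither was tested.

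The rise of cytokine, chemokine and metalloproteinase genes was weighed in the same way; medians over the 44 of 65 members that rose (1.79 with the GC and length trend removed, and 1.73 above the median of all tested genes) decide nothing, since these genes were chosen for having risen. Over whole lists the trend's removal left chemokines (adjusted p = 4.65e-05) and metalloproteinases (adjusted p = 0.00248) past the list test, which argues against it as the whole cause there. The cytokine list went from a median of 1.01 (quartiles -0.84 and 3.17) to 1.10 (-0.79 and 3.16), and its adjusted p rose past the threshold to 0.0513. Its median did not shrink, but its call was lost, so this check cannot decide whether the trend contributed to that list's rise. The median of all 65 members lay 0.89 above that of all tested genes (shift against other genes 1.08, 95% interval 0.71 to 1.48 with genes taken as independent). A few genes taking most of the counts move all genes of a library by 1 factor, which cannot set these members apart. The median of all tested genes was already 0.01 under the authors' factors, so this difference repeats the list tests. Since ZFP36, which promotes decay of mRNAs that carry the motif UAUUUAU, fell (log2 fold change -1.89), less decay could raise its targets: of the 44 members that rose 15 (34.1%) carried at least 2 such motifs in their 3' UTR, against 5 of the other 21 (23.8%), an odds ratio of 1.64 with a 95% interval of 0.454 to 6.87 (one-sided Fisher's exact p = 0.294), and among all genes those with the motif lay 0.19 above length-matched genes without it, with a bootstrap 95% interval of -0.01 to 0.30. Neither interval excludes an effect or its absence, so this hypothesis stays open, and simulated microgravity itself and differences between cultures also stay open.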
